A study of Mus musculus with 12 samples.

How the data were processed

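Gene expression was measured on Illumina mouse bead arrays of 1 colour in 12 samples, 4 per group, per the labels. The groups were the uterus and the vagina of mice that kept 1 working Trp63 copy in Pax2-cre cells (cHet uterus, cHet vagina), and the vagina of mice with both Trp63 copies floxed in those cells (cKO vagina). The labels give female mice of mixed strain at postnatal day 3, and describe each sample as a pool of 3 mice, so the replicates are pools and the p-values measure the spread between pools. Biotin-labelled cRNA was made with an amplification kit, per the labels' protocols. The position of the floxed part in the Trp63 transcript is not given in the sources used here.

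The deposited table used here holds 1 linear intensity per probe and array for 45281 probes, as processed by the authors. Its column means lay between 248.3 and 252.2, so the authors had scaled the arrays to about the same mean; the method is not given in the sources used here. No probe was centred and no background had been subtracted, as far as the values show. The median intensity was 72.3, 87.9, 90.5 and 79.2 in cHet uterus replicates 1 to 4, 93.9, 80.7, 80.1 and 85.8 in cHet vagina replicates 1 to 4, and 80.6, 74.4, 79.1 and 78.5 in cKO vagina replicates 1 to 4. A further 24 columns of per-sample values, of which 12 held signals, carried names that match no sample label and were not used. The background correction planned from detection p-values was therefore replaced by a background estimated within each array.

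The background level of an array was the mode of its intensities, and the background SD was taken from the values below that mode, mirrored around it. The modes lay between 68.9 and 90.7 and the SDs between 2.18 and 2.74. Intensities were corrected with the normexp model of limma 3.58.1 in R 4.3.3 from these estimates, given an offset of 16, quantile normalized and put on the log2 scale. A probe was above background where it passed the level that 99% of background values stay under, and was kept where it did so on at least 4 of the 12 arrays. Between 17695 and 20649 probes were above background per array, or 39.1% to 45.6%, and the number of arrays limits the precision. The platform annotation gave 1 symbol for 34885 probes, several for 18 and none for 10378. Of the annotated probes, 96 were not matched by gene identifier to the reference table of genes, and the match changed 0 symbols. Of the 20741 probes kept, 17660 had 1 symbol; the probe with the highest mean stood for its gene, which left 11178 genes, 4382 of them with over 1 kept probe.

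Group means were fitted with lmFit and eBayes of limma over all 12 arrays, which share 1 estimate of the spread with 15.8 degrees of freedom. Each adjusted p comes from limma with Benjamini-Hochberg adjustment over the genes tested, two-sided, and a gene was called where it was under 0.05. Of 32 gene lists, the 28 with at least 3 tested genes were tested with camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the lists. The design, the tests of the comparisons, the gene lists and most alternatives were fixed before the data were examined, apart from the background correction; several tests of explanations were chosen or narrowed after results were seen. The genes named were the 8 with the largest fold change in each direction among called genes whose groups did not overlap, or the first 5 for cKO vagina against cHet uterus, and up to 4 called members of each list with the largest change or else its brightest member. Trp63, Runx1, Krt5, Krt14, Krt8, Krt18, Esr1, Pgr, Hoxa13 and Pax2 were named in any case where measured; Pax2 was not tested, since its 2 probes were above background on 0 arrays. Which of the genes under this rule are printed was decided after their values were seen.

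The fit and the calls were tested on simulated log2 values with 200 changed genes among 11178, for the contrast of cKO with cHet vagina. The noise was normal, independent between genes and without sets of replicates. Background correction, normalization, filtering and the choice of probes were not part of this test. The fit recovered 13.4% of genes changed by 0.5 on the log2 scale, 80.6% of those changed by 1 and 97.0% of those changed by 2. Of its 131 calls 4 were unchanged genes. Between 0.703% and 0.993% of simulated background probes passed the background level.

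Replicate numbers run from 1 to 4 in every group. The deviations of same-numbered cHet vagina and cHet uterus arrays from their group means correlated at 0.118 to 0.431 across genes. This was over 0.1 in 4 of 4 pairs, so the numbers may pair these samples. That rests on the data alone, since no label says what a number shares. Of these 8 samples 4 correlated best with their own number, and those numbered 1 and 2 with each other's, which 2 sets of replicates would also give. The main fit used no pairs in any comparison, and a replicate block was run only as an alternative. The alternatives tried were no background correction, normexp with its own background estimate and an offset of 50, cyclic loess, medians aligned only, the authors' processed values without further normalization, other filters on dim probes, the mean of all probes of a gene, other variance models, 8 arrays in place of 12, a replicate block, a block of replicates 1 and 2 against replicates 3 and 4, each of these sets alone, and leaving out each array in turn.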

Results

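Expression was measured in 12 pools of newborn mouse tissue, 4 each of cHet uterus, cHet vagina and cKO vagina, with 3 mice in each pool. The cHet animals carried 1 floxed and 1 normal copy of Trp63, and the cKO animals carried floxed copies alone, each with a Pax2-cre transgene. Across genes, arrays of the same group correlated at 0.972 to 0.991. Median intensity per array ran from 72.3 to 93.9, and 39.1% to 45.6% of probes were above background. The first principal component, with 48.3% of the variance, separated the uterus from both vaginal groups. Replicates 1 and 2 lay apart from replicates 3 and 4 on the second, with 14.8%, in every group. Between these sets 1379 of 11178 genes differed, 612 higher and 767 lower in replicates 3 and 4, so values within each set are given beside the main results.

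**Figure D1:**
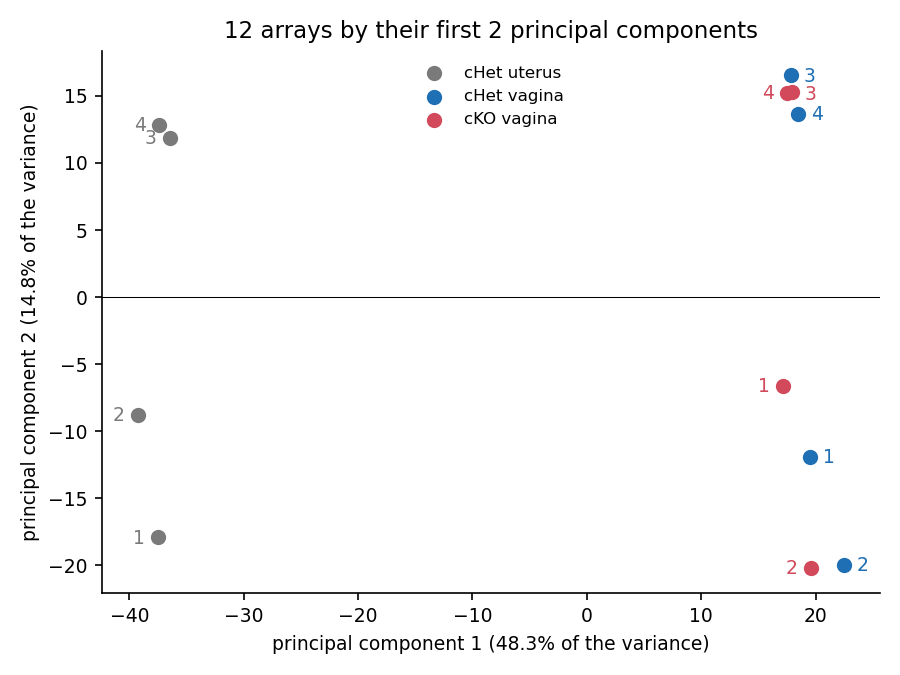
The 12 arrays by their scores on the first 2 principal components of log2 intensity, with 48.3% and 14.8% of the variance, coloured by group and numbered by replicate. Uterus and vagina part along the horizontal axis, and replicates 1 and 2 part from replicates 3 and 4 along the vertical axis.

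Trp63 encodes the transcription factor p63 of stratified epithelium, and its level in each pool was read first. In cHet vagina it stood at log2 9.74, 9.56, 9.35 and 9.71 in replicates 1 to 4. In cKO vagina it stood at 9.07, 9.72, 9.43 and 9.91. The cHet uterus had 4.54, 4.52, 4.60 and 4.75, above background in 3 of 4 pools. The cKO minus cHet vagina difference of the Trp63 probe was -0.06 (SE 0.17, adjusted p = 0.979), with -0.26 in replicates 1 and 2 and 0.14 in replicates 3 and 4. Because the deleted part of the gene is not given in the sources used here, a probe that may lie outside it checks neither the deletion nor the labels. The other Trp63 probe stayed close to background on every array and was not tested.

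The comparison of cKO with cHet vagina asked which genes depend on Trp63 in the developing vagina. Col17a1, which encodes a collagen that anchors basal cells to the basement membrane, fell most, from 8.77 ± 0.15 to 5.68 ± 0.996 (log2, SD, n = 4 each), a fold of 8.53 (log2 -3.09, SE 0.34, adjusted p = 0.000192). Its other probes had smaller falls, with -2.56 and -1.30. Dapl1, a gene of early squamous cells, fell 5.15-fold (log2 -2.36, SE 0.21, adjusted p = 1.94e-05), and Art4, a cell-surface ADP-ribosyltransferase gene, fell 5.10-fold (log2 -2.35, SE 0.17, adjusted p = 4.34e-06). Mir205hg, the host transcript of an epithelial microRNA, fell 4.89-fold (log2 -2.29, SE 0.24, adjusted p = 0.000120). Krt17, a keratin of stratified epithelium, fell 3.48-fold from 12.48 ± 0.37 to 10.68 ± 0.55 (log2 -1.80, SE 0.24, adjusted p = 0.00149). In each of these genes all 4 cKO pools lay below all 4 cHet vagina pools, which the rule that named them required. Dapl1 was above background in 3 of 4 cKO pools and Art4 in 2 of 4. Ugt1a10 fell 3.64-fold, but genes of the Ugt1a cluster share exons, so which transcript its probe read is uncertain.

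Genes of several epithelial functions fell with them. Sfn, a cell-cycle regulator of squamous cells, fell 2.96-fold (log2 -1.57, SE 0.31, adjusted p = 0.0357), and Lamb3, a laminin chain of the epithelial basement membrane, fell 2.81-fold (log2 -1.49, SE 0.29, adjusted p = 0.0335). Anxa8, an annexin of squamous epithelium, fell 2.94-fold (adjusted p = 0.00108). Hey1, a target of Notch signalling, fell 2.80-fold (adjusted p = 0.00538), by -2.04 in replicates 1 and 2 and -0.92 in replicates 3 and 4. Upk2, a uroplakin of bladder epithelium, fell 2.57-fold (adjusted p = 0.00164). Ppl, a plakin of the cornified envelope, fell 1.60-fold (adjusted p = 0.0469), while its other probes had -0.47 and -0.00047.

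A smaller set of genes rose in cKO vagina. Cxcl15, a chemokine of secretory epithelium, rose 3.46-fold from 8.48 ± 0.31 to 10.27 ± 0.13 (log2, SD, n = 4 each; log2 change 1.79, SE 0.15, adjusted p = 1.94e-05). Clca1, a secreted protein of mucous epithelium, rose 3.14-fold (log2 1.65, SE 0.26, adjusted p = 0.00582), and Cdh16, a cadherin of kidney and duct epithelium, rose 2.44-fold (log2 1.29, SE 0.23, adjusted p = 0.0219). Wscd1 rose 2.25-fold (adjusted p = 0.00552), from a cHet vagina level above background in 3 of 4 pools. Plekhs1 rose 1.97-fold (adjusted p = 0.0242), and Wif1, a secreted Wnt inhibitor, rose 1.58-fold (adjusted p = 0.0377).

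Of the basal keratins, Krt14 varied more between pools than the genes above. Krt14, a keratin of basal cells, had a mean of 10.77 ± 0.80 in cHet vagina and 8.62 ± 1.38 in cKO vagina (log2, SD, n = 4 each), a difference of -2.15 (SE 0.55, adjusted p = 0.142) that did not pass the test. With replicates 1 and 2 set apart from replicates 3 and 4 as a block, its adjusted p was 0.00114, and over 27 alternatives it ran from 0.00114 to 0.472. Its partner Krt5, above background in 3 of 4 cKO pools, had -1.11 (SE 0.30, adjusted p = 0.186), with 0.0253 under that block and 0.0253 to 0.544 over 26 alternatives; without cHet vagina replicate 3 it was 0.0341. The keratins of simple epithelium differed by less, with -0.27 (SE 0.19, adjusted p = 0.859) for Krt8 and 0.12 (SE 0.20, adjusted p = 0.961) for Krt18. Runx1, a transcription factor of developing epithelium and blood, had -0.22 (SE 0.23, adjusted p = 0.928). The oestrogen receptor gene Esr1 had 0.04 (SE 0.17, adjusted p = 0.988) and Hoxa13, a gene of the most distal tract, 0.12 (SE 0.18, adjusted p = 0.955).

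**Figure D2:**
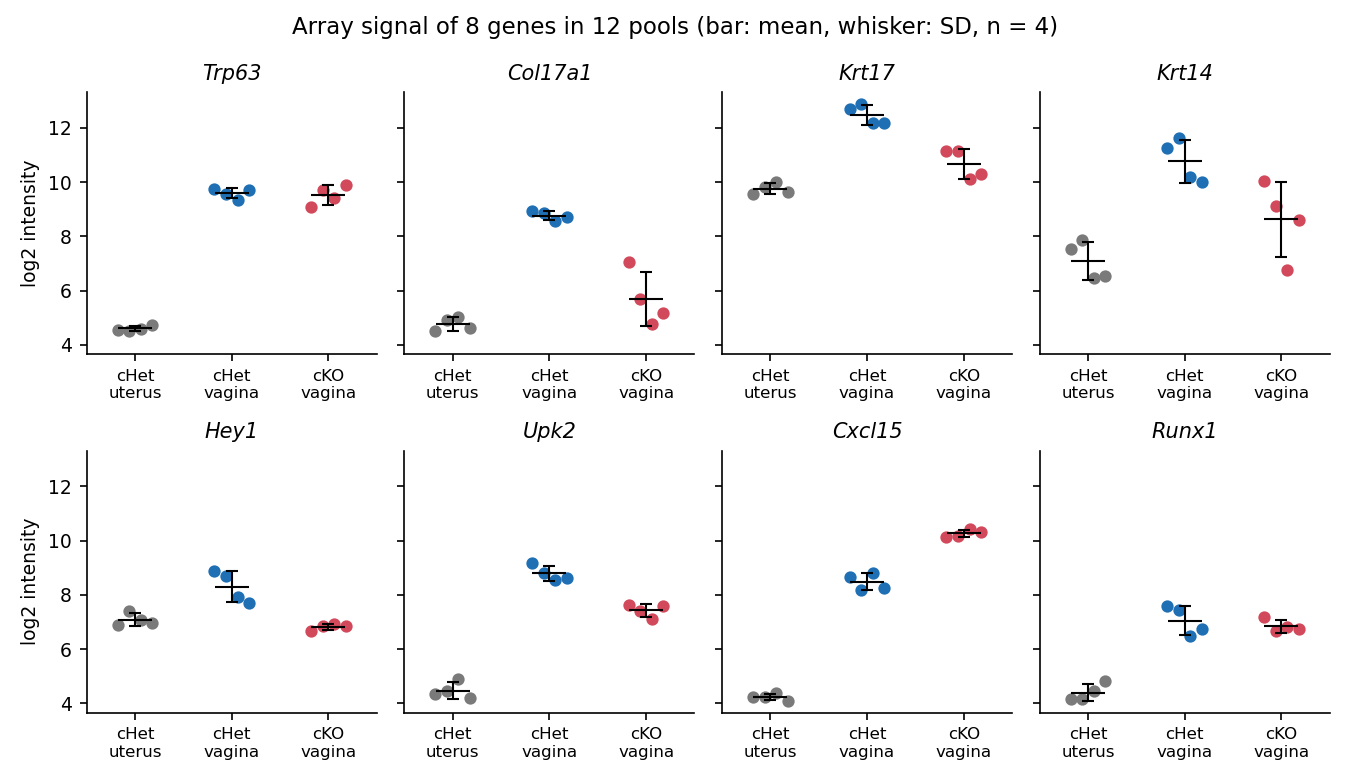
Log2 intensity of 8 genes in the 12 pools, by group, with 1 point per array, a bar at the mean and a whisker of 1 SD (n = 4). Col17a1, Krt17, Hey1 and Upk2 lie lower and Cxcl15 higher in cKO than in cHet vagina in all pools, while the Trp63 probe stays near log2 9.53 and 9.59.

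In all, 43 of 11178 genes were called between cKO and cHet vagina by limma, 6 higher and 37 lower in cKO, and 24 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 788 genes, where chance would give 559. The groups did not overlap in 484 genes, or 4.33%, where chance gives 2.86%. With the 2 sets of replicates as a block, 14 genes were higher and 80 lower. Replicates 1 and 2 alone gave 21 and 51, and replicates 3 and 4 alone gave 3 and 10. The 43 genes, chosen over these same arrays, kept their direction in both sets, and 25 and 13 of them were called again. The fold changes of the 2 sets correlated at only 0.1801 across all genes, against 0.823 between cHet vagina and cHet uterus. The count of lower genes was 17 without cHet vagina replicate 1, 19 without cHet vagina replicate 2, 19 without cKO vagina replicate 1 and 23 without cKO vagina replicate 3.

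Leaving out 1 array also decided some of the named genes. Sfn was no longer called without any of 9 arrays, namely the 4 of cHet uterus, cHet vagina replicates 1 and 2 and cKO vagina replicates 1, 3 and 4 (adjusted p = 0.0514 to 0.158). Lamb3 was lost without any of 6 arrays, namely cHet uterus replicate 3, cHet vagina replicates 1 and 2 and cKO vagina replicates 1, 3 and 4 (adjusted p = 0.0541 to 0.147). Ppl was kept only when cHet vagina replicate 4 was the array left out, and had an adjusted p of 0.0523 to 0.188 without any of the other 11. Cdh16 was lost without cHet vagina replicate 1 or 2 or cKO vagina replicate 2, 3 or 4 (adjusted p = 0.0640 to 0.0892), and Plekhs1 without cHet vagina replicate 3 or 4 or cKO vagina replicate 1, 2 or 4 (adjusted p = 0.0576 to 0.0848). Wif1 was lost without any of 9 arrays, namely cHet uterus replicates 1 and 4, cHet vagina replicates 1, 2 and 4 and the 4 of cKO vagina (adjusted p = 0.0514 to 0.118). Col17a1, Krt17, Hey1, Upk2, Cxcl15 and Clca1 stayed called whichever array was left out. Over all alternatives the adjusted p ran from 0.00177 to 0.178 for Sfn, 1.64e-05 to 0.153 for Lamb3, 0.0113 to 0.389 for Ppl, 0.000427 to 0.0969 for Cdh16, 0.00206 to 0.182 for Plekhs1 and 0.0179 to 0.780 for Wif1. It reached 0.0653 for Anxa8, 0.0738 for Hey1, 0.110 for Upk2, 0.0513 for Clca1 and 0.311 for Wscd1.

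Whole programmes were compared next, to ask which groups of genes moved together in cKO vagina. Genes of basal adhesion, which tie basal cells to each other and to the matrix, fell as a list (median log2 -0.44 over 11 genes, mean -0.66, camera adjusted p = 8.12e-07, and adjusted p = 0.0272 with an estimated correlation). Col17a1 and Lamb3 were called in it, and 3 genes adjusted over the list alone. This list was called in replicates 1 and 2 (adjusted p = 1.41e-05) and in replicates 3 and 4 (adjusted p = 0.000191), and over 21 alternatives its adjusted p ran from 9.89e-08 to 0.0272. The squamous differentiation list, with Sfn and Ppl called, fell with a median of -0.31 over 14 genes (adjusted p = 1.43e-05, but adjusted p = 0.191 with an estimated correlation), and 5 genes fell adjusted over the list alone. The urothelium list, with Upk2 called, fell with a median of -0.44 over 5 genes (adjusted p = 0.00373, but adjusted p = 0.265 with an estimated correlation), 1 of them adjusted over the list alone. The Notch list, with Hey1 called, fell with a median of -0.16 over 10 genes (adjusted p = 0.00698, but adjusted p = 0.191 with an estimated correlation), 2 of them adjusted over the list alone. The stratified keratins fell by the test (adjusted p = 0.00698, but adjusted p = 0.590 with an estimated correlation) with a mean of -0.64 but a median of -0.05 over 9 genes; Krt17 was called, and 4 genes adjusted over the list alone.

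Of the 10 tested lists of other cell types 4 were called, urothelium lower and 3 higher in cKO vagina. The red blood cell list rose with a median of 0.71 over 4 genes (adjusted p = 0.0207), the skeletal muscle list with 0.30 over 12 genes (adjusted p = 0.0222) and the leukocyte list with 0.12 over 10 genes (adjusted p = 0.0477), but none of the 3 was called with an estimated correlation (adjusted p = 0.559, 0.590 and 0.590). In cKO vagina replicate 3 the mean score of the red blood cell list was 1.84 and that of skeletal muscle 1.37 (log2, from the mean of each gene over the 12 arrays), with -0.61 to 0.04 and -0.47 to 0.67 in the other cKO pools, and without this array both lists were lost (adjusted p = 0.612 and 0.826). None of their members was called over all genes; over its list alone 1 red blood cell gene was called and 0 genes of the other lists. Hba-a1, a haemoglobin gene, had 0.74 (SE 0.26, adjusted p = 0.438) in the cKO minus cHet vagina difference.

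Of these 8 lists, camera kept only basal adhesion with an estimated correlation, as did fry (adjusted p = 0.00757). Under the block of the 2 sets of replicates the leukocyte list alone of the 8 was lost (adjusted p = 0.0517, over 21 alternatives 0.00161 to 0.797). In replicates 1 and 2 alone the skeletal muscle and red blood cell lists had adjusted p = 0.605 and 0.709, and in replicates 3 and 4 alone the Notch and leukocyte lists had 0.0607 and 0.797, where the other called lists stayed called. Fibrillar matrix was gained as higher in replicates 1 and 2 alone (adjusted p = 0.0233), and in replicates 3 and 4 alone the vaginal Hox genes as higher (adjusted p = 0.0255, over 21 alternatives 0.0255 to 0.709) and mast cells as lower (adjusted p = 0.00187). The number of lists was 3 without cHet vagina replicate 2, 5 without cHet vagina replicate 3 and 3 without cKO vagina replicate 3. Without cHet vagina replicate 2 or cKO vagina replicate 3 the stratified keratins (adjusted p = 0.238 to 0.306) and urothelium (adjusted p = 0.0994 to 0.201) were lost. Red blood cells were lost without cHet vagina replicate 2 or 3 or cKO vagina replicate 3 (adjusted p = 0.0572 to 0.612), and skeletal muscle without those or cKO vagina replicate 1 (adjusted p = 0.282 to 0.826). Leukocytes were lost without any of 6 arrays, namely cHet uterus replicate 2, cHet vagina replicates 1, 2 and 3 and cKO vagina replicates 1 and 3 (adjusted p = 0.0521 to 0.455). Fibrillar matrix was gained without cHet vagina replicate 4 or cKO vagina replicate 2 or 4 (adjusted p = 0.0215 to 0.0413), smooth muscle without cHet vagina replicate 1 (adjusted p = 0.0394) and mast cells without cKO vagina replicate 1 (adjusted p = 0.0217). Over 21 alternatives the adjusted p ran from 4.24e-07 to 0.191 for squamous differentiation, 0.000272 to 0.265 for urothelium, 0.00171 to 0.191 for Notch, 6.55e-06 to 0.590 for stratified keratins, 0.000528 to 0.709 for red blood cells and 3.60e-05 to 0.826 for skeletal muscle. For fibrillar matrix, smooth muscle and mast cells it ran from 0.0215 to 0.716, 0.0394 to 0.952 and 0.00187 to 0.897.

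The other 20 lists were not called between cKO and cHet vagina. Simple epithelium had a median of -0.10 over 17 genes (adjusted p = 0.691), the uterine Hox genes 0.04 over 6 (adjusted p = 0.808), the vaginal Hox genes 0.12 over 3 (adjusted p = 0.199) and the BMP and activin list -0.14 over 13 (adjusted p = 0.233). The lowest adjusted p among the 20 was 0.128, for fibrillar matrix, with a median of 0.16 over 14 genes. Median and mean differed in sign for proliferation (-0.07 and 0.03), interferon (-0.05 and 0.05), steroid receptors (0.02 and -0.06) and oviduct ciliated cells (-0.02 and 0.07), where the test's direction was that of the mean.

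**Figure D3:**
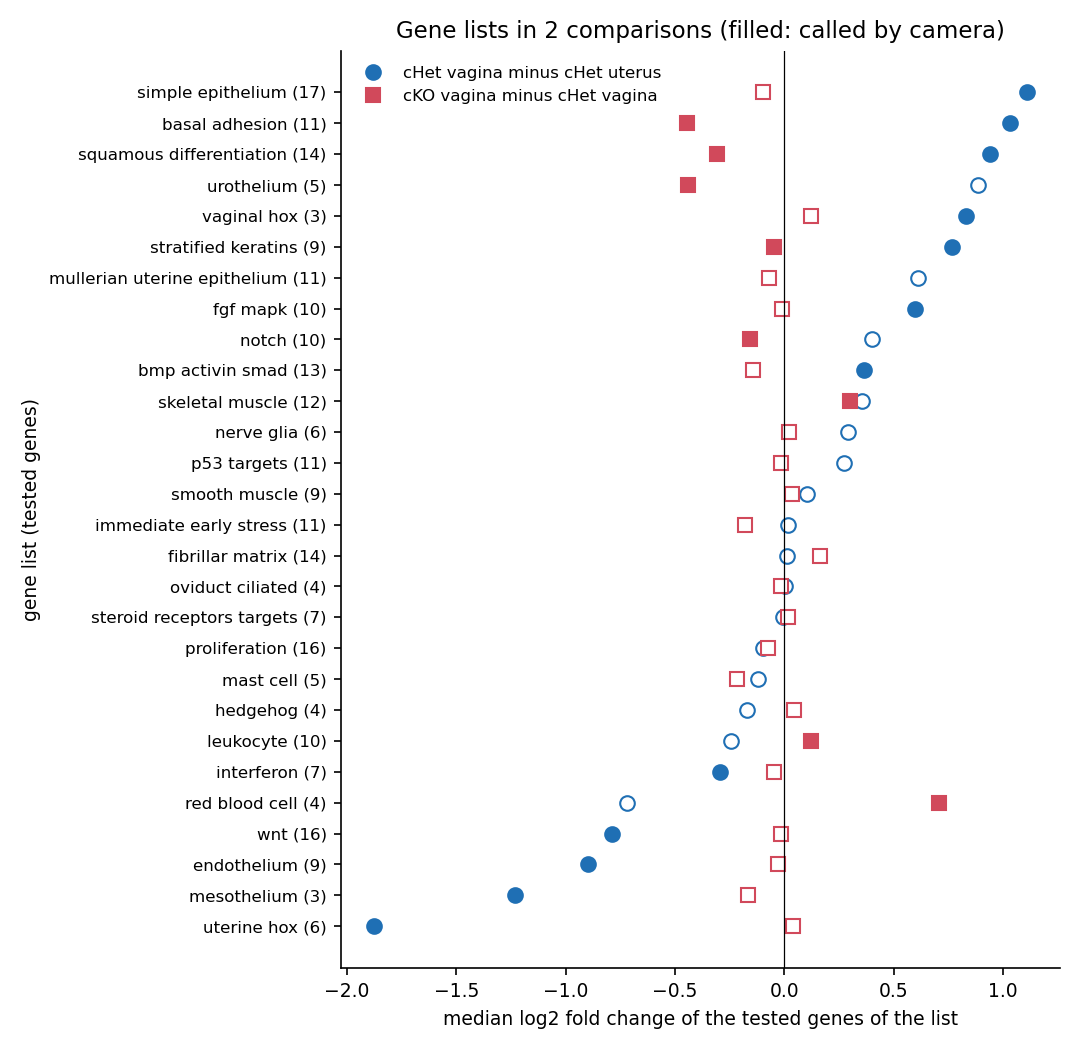
Median log2 fold change of the tested genes of 28 lists in cHet vagina minus cHet uterus (circles) and in cKO minus cHet vagina (squares), with the number of tested genes in brackets and filled symbols where camera called the list. Basal adhesion lies at 1.03 between the organs and at -0.44 in cKO vagina, while simple epithelium lies at 1.11 and -0.10.

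The comparison of cHet vagina with cHet uterus asked what sets the organs apart at this age in the control genotype. Isl1, a homeobox gene of the distal urogenital tract, was higher in vagina by 6.01 (log2, SE 0.25, adjusted p = 1.80e-10), from 4.36 ± 0.19 in uterus to 10.36 ± 0.52 (SD, n = 4 each), and above background in 1 of 4 uterus pools. Trp63 was higher by 4.99 (SE 0.17, adjusted p = 3.28e-11), a fold of 31.7, and by 3.05 to 5.12 over 26 alternatives. Upk2 was higher by 4.32, Cldn10, a tight junction gene, by 4.30 and Serpinb11, a protease inhibitor gene, by 4.23 (adjusted p = 1.80e-10, 6.50e-10 and 2.47e-08), with Upk2 and Serpinb11 above background in 1 of 4 uterus pools each, so that their differences are against a level mostly at background. Pnliprp1, a pancreatic lipase relative, and Cxcl15 were not above background in any uterus pool. With the chosen background they were at least 24.2-fold and 15.8-fold higher in vagina (adjusted p = 1.36e-08 and 3.69e-11). Over 26 alternatives their log2 differences ran from 2.72 to 5.44 and from 2.20 to 4.35. Hdc, which makes histamine, was higher by 4.08 (SE 0.37, adjusted p = 8.01e-07), with 3.11 in replicates 1 and 2 and 5.05 in replicates 3 and 4.

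Epithelial genes were among the largest differences. Krt15 was higher in vagina by 4.04, Col17a1 by 4.00, Krt14 by 3.68, Krt17 by 2.72 and Sfn by 2.65, with adjusted p of 4.02e-06, 3.21e-07, 0.000120, 5.02e-07 and 1.06e-05. Other probes of Col17a1 had 1.78 and 3.68, and Sfn was above background in 1 of 4 uterus pools. Krt5 was not above background in any uterus pool. With the chosen background it was at least 2.41-fold higher in vagina (adjusted p = 0.00115), with log2 differences of 0.54 to 2.16 over 26 alternatives. Genes of simple epithelium were higher too, with 2.07 for the claudin Cldn4, 2.16 for the splicing factor Esrp2, 1.11 for Krt8 and 1.01 for Krt18 (adjusted p = 1.69e-06, 1.87e-06, 0.000444 and 0.00180). Another Esrp2 probe had 0.62. Runx1 was higher by 2.65 (SE 0.23, adjusted p = 4.32e-07), above background in 1 of 4 uterus pools. Tspan8, a tetraspanin of epithelial cells, was higher by 3.71 (SE 0.22, adjusted p = 7.56e-09). Foxa2, a regulator of uterine glands in older mice, was at least 2.16-fold higher in vagina with the chosen background (adjusted p = 1.86e-05). Its log2 difference was 0.43 to 1.47 over 26 alternatives. Esr1 and Pgr, the receptors for oestrogen and progesterone, had -0.01 and -0.24 (adjusted p = 0.985 and 0.429).

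Stromal signals and positional genes also differed. The growth factor genes Fgf10, Bmp4, Inhba and Fgf7 were higher in vagina by 3.56, 2.56, 2.06 and 1.92 (adjusted p = 1.53e-08, 1.54e-07, 1.18e-06 and 4.53e-06), with Fgf10 above background in 1 of 4 uterus pools. Other probes of Fgf10 had 0.42 and 3.11, and another probe of Bmp4 had 0.98. Of the smooth muscle genes, Actg2 was higher by 3.64 and Myh11 by 2.09, while Des was lower, with -1.36 (adjusted p = 1.84e-07, 0.000163 and 0.00215). Hox genes of the middle tract were lower in vagina, with -3.50 (SE 0.15) for Hoxd10, -3.46 (SE 0.23) for Hoxd9, -3.38 (SE 0.14) for Hoxd4 and -2.53 (SE 0.23) for Hoxa11 (adjusted p = 1.80e-10, 2.47e-08, 1.80e-10 and 6.51e-07), and Hoxd4 was above background in 1 of 4 vagina pools. Distal Hox genes were higher, with 1.34 for Hoxd12 and 0.83 for Hoxa13 (adjusted p = 0.000124 and 0.00316, with up to 0.271 over 26 alternatives for Hoxa13), above background in 3 of 4 and 2 of 4 uterus pools. Another Hoxa13 probe had 0.21. Upk3b and Msln, genes of the mesothelium that covers the uterus, had -3.71 and -1.92 (adjusted p = 1.42e-08 and 1.38e-06), with Msln above background in 2 of 4 vagina pools. Amhr2, the receptor for anti-Müllerian hormone, had -3.54 (SE 0.17, adjusted p = 6.82e-10), and its other probes -1.40 and -1.24. Scin, Lbhd2 and Serpinb6b had -3.70, -3.13 and -3.09 (adjusted p = 7.50e-10, 4.49e-08 and 6.50e-10), with Scin above background in 3 of 4 vagina pools. The secreted Wnt regulators Notum and Rspo3 were lower, with -1.33 and -1.30, while Wnt7b was higher, with 1.31 (adjusted p = 1.16e-05, 2.49e-05 and 9.86e-05).

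Between cHet vagina and cHet uterus limma called 2076 genes, 1053 higher and 1023 lower in vagina, of which 439 and 285 differed at least 2-fold. With the authors' processed values 1000 were higher and 561 lower. The groups did not overlap in 2414 genes, or 21.6%, where chance gives 2.86%. Replicates 1 and 2 alone gave 681 and 650 genes, and replicates 3 and 4 alone gave 1100 and 850. The 2076 genes, chosen over these same arrays, kept their direction in both sets. Across all genes the fold changes of the 2 sets correlated at 0.823. The genes named above stayed called whichever array was left out, except Esr1 and Pgr, which were not called.

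Camera called 12 lists between the organs. Simple epithelium was higher in vagina (median 1.11 over 17 genes, adjusted p = 3.90e-11, and adjusted p = 0.0230 with an estimated correlation), with 14 genes called and 16 adjusted over the list alone. Basal adhesion was higher (median 1.03 over 11 genes, adjusted p = 3.22e-06, and adjusted p = 0.0230 with an estimated correlation), with 8 genes called and 8 adjusted over the list alone. The FGF list was higher (median 0.60 over 10 genes, 0.56 with bounds, adjusted p = 0.000270, and adjusted p = 0.0230 with an estimated correlation), with 6 genes called and 7 adjusted over the list alone. The uterine Hox list was lower (median -1.88 over 6 genes, adjusted p = 3.24e-09, and adjusted p = 0.00312 with an estimated correlation), with 6 of 6 genes called, also adjusted over the list alone.

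The other 8 lists between the organs were lost with an estimated correlation. Squamous differentiation was higher (median 0.94 over 14 genes, 0.79 with bounds, adjusted p = 4.10e-05, and adjusted p = 0.0933 with an estimated correlation), with 10 genes higher and 1 lower adjusted over the list alone. The stratified keratins were higher (median 0.77 over 9 genes, 0.45 with bounds, adjusted p = 0.000448, and adjusted p = 0.264 with an estimated correlation), with 5 genes adjusted over the list alone. The vaginal Hox list was higher (median 0.83, adjusted p = 0.00575, and adjusted p = 0.149 with an estimated correlation), with 3 of 3 genes adjusted over the list alone, and so was the BMP and activin list (median 0.36, 0.15 with bounds, adjusted p = 0.0135, and adjusted p = 0.0757 with an estimated correlation), with 5 higher and 2 lower adjusted over the list alone. Endothelium was lower (median -0.90, adjusted p = 3.91e-05, and adjusted p = 0.0757 with an estimated correlation), with 8 genes adjusted over the list alone, of which Esam, a junction gene of vessels, had -1.22 (SE 0.16, adjusted p = 4.69e-05). Mesothelium was lower (median -1.23, adjusted p = 0.00295, and adjusted p = 0.0888 with an estimated correlation), with 2 genes adjusted over the list alone. The Wnt list was lower (median -0.79, -0.66 with bounds, adjusted p = 0.0121, and adjusted p = 0.0892 with an estimated correlation), with 3 genes higher and 10 lower adjusted over the list alone. The interferon list was lower (median -0.29, adjusted p = 0.0319, and adjusted p = 0.101 with an estimated correlation), with 3 genes adjusted over the list alone, among them Rsad2 and Oasl2, which had -1.75 and -1.68 (adjusted p = 0.00136 and 2.14e-06), Rsad2 above background in 3 of 4 vagina pools. It was lost without cHet uterus replicate 1 or cHet vagina replicate 3 (adjusted p = 0.0619 to 0.0633) and in replicates 3 and 4 alone (adjusted p = 0.0650), where fibrillar matrix was gained as higher (adjusted p = 0.0283, over 21 alternatives 0.0283 to 0.923). In replicates 1 and 2 alone Notch was gained as higher and red blood cells and leukocytes as lower (adjusted p = 0.00819, 0.0144 and 0.00436). Notch was gained without cHet uterus replicate 3 (adjusted p = 0.0434), red blood cells without cKO vagina replicate 3 (adjusted p = 0.0436) and leukocytes without cHet uterus replicate 3 or 4 or cHet vagina replicate 4 (adjusted p = 0.0278 to 0.0339), where 21 alternatives gave 0.00337 to 0.365, 0.0144 to 0.588 and 0.00436 to 0.650. For each of the 12 called lists the highest adjusted p over 21 alternatives was the value with an estimated correlation, and the lowest lay between 8.00e-14 for simple epithelium and 0.00104 for the vaginal Hox genes. Median and mean differed in sign for steroid receptors (-0.01 and 0.47) and mast cells (-0.12 and 0.69), neither of them called, where the test's direction was that of the mean.

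The comparison of cKO vagina with cHet uterus asked what still parted the cKO vagina from the uterus. Isl1 was higher in cKO vagina by 6.00 (log2, SE 0.25, adjusted p = 1.84e-10), Trp63 by 4.93 (SE 0.17, adjusted p = 1.99e-11) and Cldn10 by 4.62 (SE 0.21, adjusted p = 2.88e-10). Cxcl15 and Pnliprp1 were at least 54.8-fold and 29.7-fold higher with the chosen background (adjusted p = 3.86e-13 and 6.46e-09). Their log2 differences were 3.79 to 6.14 and 2.98 to 5.56 over 26 alternatives. Runx1 was higher by 2.44 and Upk2 by 2.96 (adjusted p = 1.34e-06 and 1.04e-08). Isl1, Runx1, Upk2 and Sfn were above background in 1 of 4 uterus pools each and Trp63 in 3 of 4. Upk3b, Hoxd9, Amhr2, Scin and Hoxd10 were lower, with -4.26, -3.77, -3.73, -3.58 and -3.40 (adjusted p = 3.46e-09, 9.49e-09, 3.57e-10, 1.35e-09 and 2.80e-10). Krt17 was higher by 0.92 (SE 0.24, adjusted p = 0.0117), Itgb4, an integrin of basal cells, by 1.15 (SE 0.20, adjusted p = 0.000607) and Krt8 by 0.84 (SE 0.19, adjusted p = 0.00475). Sfn was higher by 1.08 (SE 0.31, adjusted p = 0.0215), but not without cHet uterus replicate 2 or 3 or cKO vagina replicate 1 or 2 (adjusted p = 0.0529 to 0.0759, over 26 alternatives 0.000327 to 0.267). Krt14 had 1.53 (SE 0.55, adjusted p = 0.0663), and 0.00236 without cKO vagina replicate 3, with 0.000455 to 0.214 over 27 alternatives. It was also called under the replicate block and under the block of the 2 sets of replicates. The adjusted p reached 0.151 for Krt17 and 0.0502 for Itgb4.

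In this comparison limma called 2049 genes, 997 higher and 1052 lower in cKO vagina, of which 382 and 305 differed at least 2-fold. With the authors' processed values 1116 were higher and 604 lower. The groups did not overlap in 2417 genes, or 21.6%, where chance gives 2.86%. Replicates 1 and 2 alone gave 623 and 689 genes, and replicates 3 and 4 alone gave 1107 and 845. Of these genes 1586 were called in the same direction between cHet vagina and cHet uterus and 1 in the opposite direction. Of the 1586, 791 were higher and 795 lower, where independent lists would have shared 93.9 and 96.3. The fold changes of both comparisons correlated at 0.909 across genes, which are not independent replicates, against 0.5001 in 50 simulations of unchanged vaginal groups that shared the uterus arrays, and the covariance was 0.272 against 0.0197. With the uterus arrays split so that each comparison used its own pair, the correlation was 0.741 to 0.861, the covariance 0.243 to 0.264 and the genes called in the same direction 959 to 1022 over 6 assignments. Camera called 10 lists, 6 up and 4 down, of which simple epithelium (median 1.15, adjusted p = 0.0398 with an estimated correlation) and the uterine Hox genes (median -1.80, adjusted p = 0.00314 with an estimated correlation) were kept with an estimated correlation. The 8 lost were stratified keratins, basal adhesion, squamous differentiation, vaginal Hox and FGF, all higher in cKO vagina, and Wnt, endothelium and mesothelium, all lower, with adjusted p = 0.524, 0.117, 0.388, 0.117, 0.0692, 0.0828, 0.0825 and 0.0849 with an estimated correlation. Median and mean differed in sign for smooth muscle (-0.11 and 0.53) and mast cells (-0.34 and 0.39), neither of them called.

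Setting the change in cKO vagina beside the organ difference asked how far the cKO vagina moved toward the uterus. Of the 43 genes called in cKO vagina, 35 were also called between the organs, and 33 of those, or 94.3% (exact binomial interval 80.8% to 99.3%, which treats genes as independent), moved toward the uterus level. Col17a1, Krt17, Sfn, Anxa8, Lamb3, Hey1 and Upk2 were among the 33, each higher in vagina than uterus and lower in cKO vagina. The 2 that moved away were Cxcl15 and Clca1, higher in vagina than uterus and higher still in cKO. Over the 35 genes, which were selected by their call in cKO, a median of 64.9% of the organ difference was lost, and of the 33 genes 18 were still called higher than in uterus, 1 was called lower and 14 were not called. Upk2 lost 31.5%, Krt17 66.1%, Col17a1 77.3% and Lamb3 102.9% of its organ difference, where the uterus level of Upk2 was above background in 1 of 4 pools.

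These comparisons share the cHet vagina arrays, which by itself draws fold changes toward the uterus. With a cKO group simulated as unchanged there were 0.0600 shared calls on average, at most 1, against the 35 observed, and independent lists would have shared 3.49 genes that fell and were higher in vagina, against 33. Among all genes called between the organs, 63.2% moved toward the uterus, against 60.4% (highest 62.3%) in 50 simulations of an unchanged cKO group. The slope of the cKO change on the organ difference over these 2076 genes was 0.0930 toward the uterus, against 0.0405 in the simulations. Other splits of the real vaginal arrays called up to 6 genes with the sets of replicates balanced, and 288 when split by set. The simulated counts and shares may therefore understate what chance gives. Across all genes the correlation was 0.263, against 0.502 for unchanged groups in both comparisons, and the covariance was 0.0339 against 0.0199. With the cHet vagina arrays split so that each comparison used its own pair, 75.0% to 94.7% of shared calls moved toward the uterus over 6 assignments, with 13 to 116 genes called in cKO. In that split 50.03% to 61.8% (median 54.4%) of all genes called between the organs moved toward the uterus, with slopes of 0.0246 to 0.0791, and across all genes the correlation was -0.0025 to 0.196 and the covariance -0.00040 to 0.0269. The 116 genes came from cHet vagina replicates 1 and 2 in the cKO comparison, and 50.03% and -0.0025 from replicates 3 and 4, which mix in the difference between the sets. Where each pair held 1 pool of either set, 13 to 20 genes were called in cKO. There 53.2% to 61.8% moved toward the uterus, and the correlation was 0.081 to 0.196. In replicates 1 and 2 alone the share was 94.0% of 50 genes and in replicates 3 and 4 alone 83.3% of 12.

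**Figure D4:**
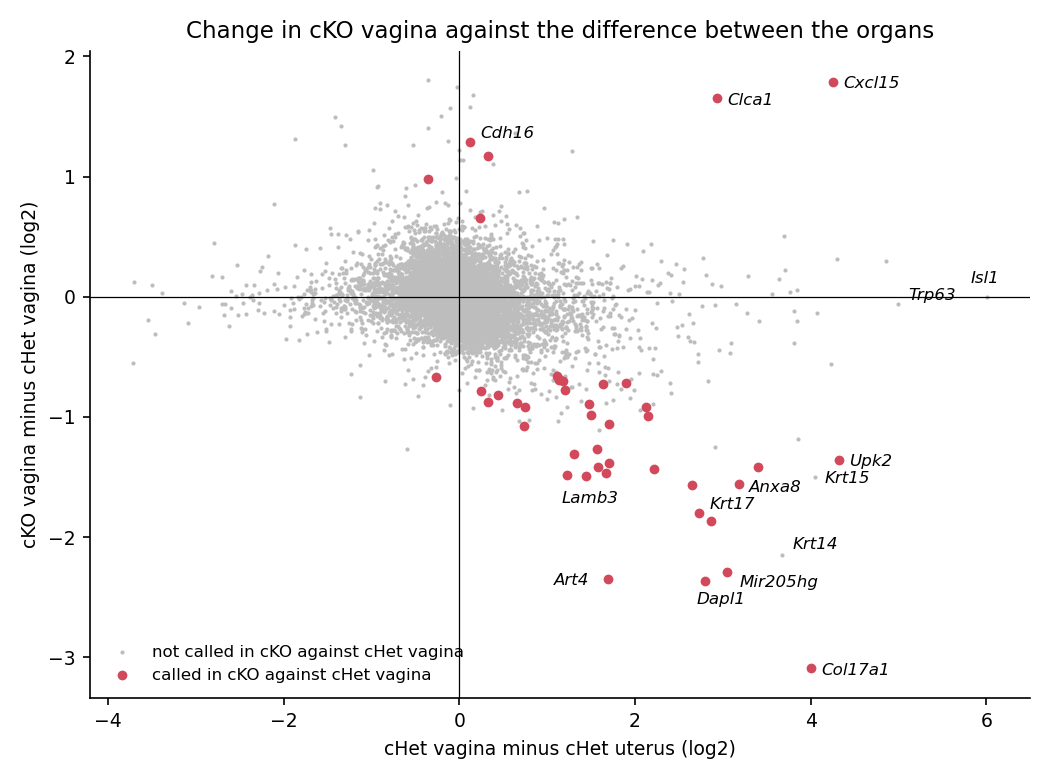
Log2 fold change of cKO minus cHet vagina against that of cHet vagina minus cHet uterus, with 1 point per gene for 11178 genes and the 43 genes called in cKO vagina in red. Most red points lie at the lower right, 33 of the 35 called in both comparisons moved toward the uterus, and Cxcl15 and Clca1 lie at the upper right.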

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

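The splits of the arrays were tests set before their results were seen. The tests of swapped labels, of epithelium, of where the pieces were taken, of urothelium, of the probe's position, of the background level, of other cell types and of splits that balance the sets were chosen only after the result was seen. In 219 groups of 4 pools, 9 held a pool far from the others by Dixon's criterion, where chance gives 10.95. Clca1 had 4.54 in cHet uterus replicate 3, with 4.21 to 4.24 in the others. Tnnt1, a troponin gene, had 9.55 in cHet uterus replicate 2, with 9.07 to 9.15 in the others. Fcer1g, a leukocyte gene, had 7.78 in cHet uterus replicate 1, with 6.91 to 6.999 in the others, and 6.66 in cKO vagina replicate 2, with 7.39 to 7.54. Wscd1 had 4.84 in cHet vagina replicate 4, with 4.51 to 4.56 in the others, and Des had 8.52 in cHet vagina replicate 1, with 7.24 to 7.44. Cdh16 and Wif1 had 9.66 and 5.18 in cKO vagina replicate 1, with 10.23 to 10.34 and 5.31 to 5.32 in the others. Rsad2, an interferon-induced gene, had 6.56 in cKO vagina replicate 3, with 4.51 to 4.73 in the others. Among 3081 probes with no gene name here, 7 were lower and 0 higher in cKO than cHet vagina by limma, by -1.05 to -0.77.

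Col17a1, Krt17 and 35 other genes fell in cKO vagina, with a median of -1.07 over the 37. Less epithelium in the cKO pieces would lower the genes of simple epithelium too, but their median was -0.10 (SD 0.32, -0.44 to 0.71, 17 genes). If these genes kept their level per epithelial cell, which was not tested, this argues against a loss of epithelium as a whole large enough to give -1.07. The -1.07 comes from genes chosen because they fell, so a smaller loss stays open, and single kinds of epithelial cell were not tested. Pieces taken nearer the uterus would shift Hox genes by the same share as the genes that fell, which was 65.0%. The 9 Hox genes lost a median of -1.20% of their organ difference (SD 28.5), which argues against a shift of that share. This share too comes from genes chosen because they fell. Less urothelium may also lower genes, and the uroplakins had a median of -0.44 (SD 0.49), with all 5 below 0; 2 of the 5 were higher in uterus than vagina and so do not report urothelium here, which leaves it open. Loss of Trp63 function in Pax2-cre cells, which the design names, may be the cause and was not tested apart from these.

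Other groupings of the arrays leave the size of that pattern open. Of the 35 splits of the 8 arrays into 4 and 4, 2 gave as many genes in 1 direction as the 37 lower genes, the real split included, and 3 gave as many as the 6 higher genes, so chance was not excluded for either; the highest other count was 152. That split followed replicates 1 and 2 against replicates 3 and 4 and called 288 genes, several times the 43 of the real split, which points to a structure of the arrays; with those sets as a block 14 genes were higher and 80 lower. Among the 18 splits that put 2 arrays of each set on either side, too few for a share under 0.05, the highest other total was 6 genes against 43, and the highest other number of lists 10 against 8. For the 8 lists, 7 of 35 splits gave as many and the highest other gave 11, so chance was not excluded; under the block of the 2 sets 7 lists were called. Between cHet vagina and cHet uterus, 1 of 35 splits, the real one, gave as many as 1053 higher genes, 1023 lower genes or 12 lists. The highest others were 27 genes and 10 lists. That share is under the 0.05 set beforehand, but it is the smallest that 35 splits can give, and they ignore possible pairs of the same number. Among the 8 splits that part all pairs, too few for a share under 0.05, the highest others were 0 genes in total against 2076 and 10 lists against 12. Between cKO vagina and cHet uterus, 1 of 35, the real one, gave as many as 997 higher or 1052 lower genes, with 0 as the highest other. This again is under 0.05 at the smallest share that 35 splits can give.

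The Trp63 probe stood at 9.53 in cKO and 9.59 in cHet vagina while Col17a1 and Lamb3 fell. Some labels swapped between cKO and cHet vagina would put arrays in each other's range, which occurred in 2 of 3 epithelial lists. By basal adhesion 0 arrays scored in the other group's range, with -0.18 to 0.11 in cKO and 0.44 to 0.78 in cHet vagina, but this list was picked after it was seen to part the groups. By stratified keratins 4 arrays did, with -0.71 to 0.83 and 0.30 to 1.37, and by squamous differentiation 2 arrays, with -0.20 to 0.12 and 0.094 to 0.75, so these lists do not decide. A swap of some labels would make another split of the arrays the true one. The labelled split called 43 genes and the others at most 6, apart from 288 for the sets of replicates, which also part the uterus pools. These counts, weighed after they were seen, argue against a swap of some labels. An exchange of all labels gives the same counts and stays open. A probe outside the deleted part would keep its level, and the change was -0.061; this could be the cause, but cannot be told apart from a transcript that was never shortened, since the deleted part is not given in the sources used here.

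Replicates 1 and 2 differed from replicates 3 and 4 in 1379 genes in a fit over the 3 groups, and no label names what they share. The background level of the arrays could differ between the sets, but 9 of 12 arrays had a mode in the range of the other set, where 0 did so on the second principal component, which argues against the level as the cause. The modes had means of 78.1 and 78.4 (SD 8.46 and 5.01). A different share of other cell types may also part them; 0 of 10 lists of other cell types were called between the sets, and the lowest adjusted p was 0.0804, which does not exclude it. Of the 28 lists the stratified keratins alone were called between the sets, lower in replicates 3 and 4 (median -0.64, adjusted p = 0.000894, but adjusted p = 0.790 with an estimated correlation), and the keratins are among the genes whose calls change under the block. The labels give postnatal day 3 for every pool. Differences in litter, preparation or age within that day stay open and were not tested.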

How the results depend on the processing

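The blocks and sets of replicates 1 and 2 against replicates 3 and 4, the offset of 50 and the split of the uterus arrays were alternatives chosen only after the data were seen; the cause was not tested where a value below moved, unless the alternative itself used fewer arrays or a higher threshold. No named gene or list had the opposite sign of the chosen settings under an alternative, where either of them called it. Values not called could change sign, as Trp63 did in cKO vagina. Between alternatives mast cells in cKO vagina were called lower in replicates 3 and 4 alone, but were higher, not called, in replicates 1 and 2 alone. Between cKO vagina and cHet uterus, 1574 of the 1575 called genes tested with probes above background in all 12 arrays kept their direction. Signal over background limits the dim genes, and slide as a block was not run, since the files give no slide. Of 1475 values of named genes under alternatives other than leaving out an array, 1400 kept their direction and side of the threshold, 54 fell short of it, 13 newly passed it and 8 moved.

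Genes higher and lower in cKO than cHet vagina numbered 2 and 23 with probes above background in all 12 arrays, a filter that tests fewer genes and leaves no value for Trp63. With the authors' processed values 24 were lower. A fold of at least 2 left 20 lower. Arrays 1 and 2 alone gave 21 higher, and arrays 3 and 4 alone gave 3 and 10. With the replicate block 13 were higher and 64 lower, and with the block of the 2 sets 14 and 80; either block called the 43 genes again, and the replicate block also called fibrillar matrix (adjusted p = 0.0459). Same-numbered cKO and cHet vagina arrays correlated over 0.1 in 3 of 4 pairs (0.0663 to 0.492), and 4 of 8 samples correlated best with their own number. For cKO vagina and cHet uterus this was 3 of 4 pairs (0.0741 to 0.310) and 3 of 8 samples. These values lie close to those of cHet vagina and cHet uterus, and arrays of different groups within a set of replicates had a median of 0.205. The numbers therefore neither show nor exclude pairs in any comparison. For cHet vagina against cHet uterus the replicate block gave 1277 higher and 1201 lower genes. It changed no call of a list or of a gene named in the text for this comparison.

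Between cHet vagina and cHet uterus, arrays 1 and 2 alone gave 681 higher and 650 lower, a fold of at least 2 gave 439 and 285, and the authors' values gave 561 lower. Between cKO vagina and cHet uterus these gave 623 and 689, 382 and 305, and 604 lower. Trp63 in cKO vagina had 0.015 with the authors' values, 0.0067 with array quality weights and 0.14 in arrays 3 and 4 alone. Lists called in cKO vagina numbered 1 with an estimated correlation and 1 with fry, and between the organs 4 with an estimated correlation. The share of shared calls toward the uterus was 75.0% with cHet vagina arrays 2 and 4 in the cKO comparison.

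Leaving out 1 array gave 4 to 8 genes higher and 17 to 42 lower in cKO vagina, 883 to 1083 and 835 to 1030 between the organs, and 839 to 1015 and 840 to 1070 between cKO vagina and uterus. It gave -0.19 to 0.094 for Trp63, 3 to 9 lists in cKO vagina, 11 to 14 lists between the organs and 88.5% to 95.1% of shared calls toward the uterus. The lowest count of 17 was without cHet vagina replicate 1; it was 19 without cHet vagina replicate 2 or cKO vagina replicate 1 and 23 without cKO vagina replicate 3. The 3 lists were without cHet vagina replicate 2 or cKO vagina replicate 3, with 5 without cHet vagina replicate 3.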

Other observations

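The test on genes near Trp63 was chosen only after the result was seen. Beyond the genes above, the 43 called genes held other genes, named here after their values were seen. Egfr, the receptor for epidermal growth factor, fell by 0.91 in cKO vagina (log2, SE 0.15, adjusted p = 0.0110, n = 4 each), and Tfap2c, a transcription factor of early squamous cells, fell by 0.78 (SE 0.15, adjusted p = 0.0301). Trim29, a gene of basal epithelium, fell by 1.44 (SE 0.22, adjusted p = 0.00594), and Sox21, a transcription factor of epithelial cells, by 1.06 (SE 0.19, adjusted p = 0.0235). Cbr2, a carbonyl reductase gene, fell by 1.41 (SE 0.21, adjusted p = 0.00538), yet stayed 1.98 above cHet uterus (SE 0.21, adjusted p = 5.49e-06).

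Krt15, outside the naming rule for this comparison and chosen after its values were seen, had -1.50 in cKO vagina (SE 0.43, adjusted p = 0.232), with 0.0254 under the block of the 2 sets of replicates, 0.0293 under the replicate block and 0.0198 to 0.632 over 27 alternatives, beside Krt14 with -2.15 and Krt5 with -1.11. Of the 33 genes that fell from a higher level in vagina, 7 had a mean below the uterus in cKO vagina, with 100.1% of the organ difference lost by Camk4, 102.9% by Lamb3, 121.2% by Hey1, 122.6% by Egfr, 135.5% by Btbd11, 138.8% by Art4 and 145.5% by Slco2a1. Of these Art4 alone was called below the uterus (log2 -0.66, SE 0.17, adjusted p = 0.0125), while Adam28 lost 37.7% and Slc34a2 lost 43.2%. Tnnt1, a slow muscle troponin gene, was lower in vagina than uterus by -1.73 (SE 0.20, adjusted p = 7.40e-06) and had 0.05 in cKO vagina (SE 0.20, adjusted p = 0.986).

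A strain segment around Trp63 carried with the floxed allele could place called genes near Trp63, since the mice were of mixed strain. Of the 40 tested genes nearest to Trp63, 0 were called, where chance gives 0.154, so this count decides little. The Trp63 chromosome held 1 called gene, Ppl, or 2.33% of the calls against 3.27% of the tested genes. Its share of unadjusted p under 0.05 was 11.5%, the highest of 20 chromosomes, against 7.05% of all genes. That share was 7.50% within 20 tested genes on either side of Trp63 and 6.25% from 21 to 60, then 15.0% from 61 to 120 and 12.9% farther away. The segment cannot be told apart from chance here, since the strains of the pools are not given in the sources used here.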
